A study of Mus musculus with 10 samples.

How the data were processed

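Kidney cortex depleted of glomeruli was taken from 24-week-old BKS mice, 5 db/db and 5 db/m, and each mouse gave 1 Affymetrix mouse genome array, per the labels. The mice are separate animals, since the titles number them within each group, and no pooling is stated. RNA was extracted with an RNeasy kit, per the series design text. The authors deposited log2 values made with RMA, per the submitters' processing notes; its version is not given in the sources used here. RMA as usually run corrects background, normalises quantiles across arrays and summarises probes, and the log2 scale was checked on the range of the values. The deposited table held 1 value per Entrez Gene ID, so the probes had been regrouped by gene, and which regrouping was used is not given in the sources used here. The values lay between 2.50 and 14.5 with medians of 8.46 to 8.66, and were used as deposited, with no further scaling.

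The table held 16539 rows, of which 64 were Affymetrix control rows and 16475 were genes. Of the gene rows 15780 carried 1 symbol in the supplied probe annotation, 0 carried several and 695 were not listed there; the latter were tested but not named. By Entrez ID 15752 of the symbols matched the RefSeq gene table. The design had stated that every row would be tested; the control rows were left out because they are not genes, and including them gave the same counts, 488 higher and 584 lower. No 2 arrays were copies of each other, since the smallest of the 45 largest pairwise differences was 3.07 log2 units. No filter on dim genes was applied, and arrays give no counts, so no counting intervals were computed.

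The groups were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes without trend, two-sided, as db/db minus db/m, and p values were adjusted with Benjamini-Hochberg over all 16475 genes, with a threshold of 0.05. Lists of genes were tested with camera at a preset correlation of 0.01, adjusted over the 46 lists, and again with an estimated correlation and with fry, which asks of each list by itself whether its genes move one way. The 46 lists cover energy metabolism, other pathways and cell types. Counts in a list are given over all genes and adjusted over the list alone. The tests, lists and alternatives were fixed before the data were examined, except where the text says otherwise. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

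Genes were named by a rule. It took Lepr, then the 10 largest rises and 10 largest falls among genes past the threshold with the groups apart, then up to 4 members per list past the threshold with the largest change, or the member with the lowest adjusted p where no member passed. One item of the rule is not reported here. Slc7a13, Slc5a1, Slc22a13, Aqp1, Slc5a2, Lcn2, Havcr1, Cpt1b, Bcat2, Pdk4, and the genes named for db/db 1 alone, were added after their values were seen. Of 76 named genes past the threshold 47 kept the call in all 10 fits that left out 1 array, 29 lost it in at least 1, and 0 changed sign by limma.

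Alternatives were the mouse number as a replicate block, dim genes left out (the lowest 25% by mean), quantile normalisation repeated, arrays centred on their medians, eBayes with trend and robust settings, array weights, each array left out in turn, windows of 10 and 40 Mb in place of 20 Mb around Lepr, at least a 1.5-fold change, and an adjusted p under 0.01. Fits with the control rows, without db/db 1 and 2, and with both the block and db/db 1 left out, and calls near Lepr without db/db 1, were added after seeing the data. Added lists of male-biased, female-biased, podocyte, glomerular and chaperone genes were compared with an exact permutation test of the array means. A test on simulated data set 200 of 16475 genes to change in arrays with the observed spread. With all 10 arrays limma recovered 42% of the changes of 0.5 log2 units and 89% of those of 1 log2 unit, with 1 false call. Without db/db 1 it recovered 54% and 90%, with 6 false calls, and 0 calls had the wrong sign in either case. These rates hold for the simulated setting alone. In it 0 lists were called besides the list set to shift, whereas 74 of 100 splits of the real arrays gave at least 13 called lists.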

Results

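Gene expression was measured in kidney cortex depleted of glomeruli from 24-week-old mice on the BKS background. The db/db group held 5 diabetic mice, which carry a mutation of the leptin receptor gene Lepr on both copies, and the db/m group held 5 littermates without diabetes. Each mouse gave 1 Affymetrix array, and the values were log2 expression levels for 16475 genes. The array medians lay between 8.46 and 8.66, and the number of arrays limits the precision of every value. The series title asks how metabolism and nutrient flux change in tissues with diabetic complications, so db/db was compared with db/m, first over all genes and then over lists for energy metabolism, other pathways and cell types. Changes are given as db/db minus db/m on the log2 scale with their standard error, for 5 mice per group, and means are given with their SD.

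One db/db mouse, number 1, differed from the other mice in a large set of inflammatory and injury genes. Saa1, an acute-phase protein gene, was above the db/m mean by 9.88 in this mouse, the neutrophil chemokine gene Cxcl5 by 7.92, and the tubular injury genes Lcn2 and Havcr1 by 6.88 and 6.66. Saa1 and Cxcl5 were near background in db/m, so their differences are approximate. In this array 746 genes were more than 4-fold above the db/m mean and 112 more than 4-fold below it, against at most 107 genes in any other db/db array. Its Pearson r with the other 9 arrays, across genes, was 0.938 to 0.962, while the other arrays correlated with each other at 0.985 or more. The first principal component, with 59.4% of the variance, separated this mouse from the others, and the second, with 18% of the variance, placed the other 4 db/db mice apart from the db/m mice. Results are therefore given with all 10 arrays, as planned, and again without db/db 1.

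**Figure D1:**
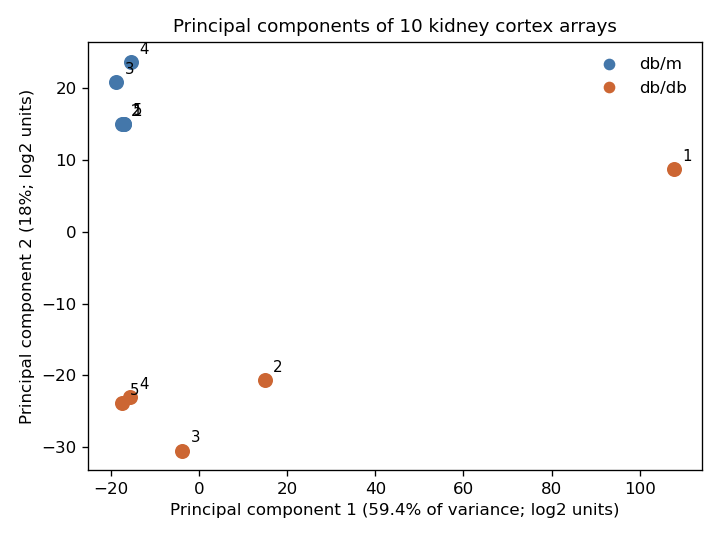
Principal component 1 (59.4% of the variance) and principal component 2 (18%) of the 10 arrays, in log2 units, with 1 point per mouse labelled with its number. The db/db mouse 1 lies at 108 on component 1 and the other 9 mice lie between -18.8 and 14.9.

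The 10 largest falls included transporter and lipid enzyme genes. Slc22a7, an organic anion transporter gene, fell from 12.30 ± 0.46 to 7.13 ± 0.86, a 35.9-fold drop (log2 change -5.17 ± 0.39, adjusted p = 0.000232). Slco1a1, another organic anion transporter gene, fell 26.2-fold (-4.71 ± 0.46, adjusted p = 0.00051). Alox15, which encodes a lipoxygenase of polyunsaturated fatty acids, fell 15.9-fold (-3.99 ± 0.21, adjusted p = 2.82e-05), and Neurog2, a transcription factor gene known from neurons, fell 13.4-fold (-3.75 ± 0.18, adjusted p = 2.42e-05), to 3.70 in db/db, below the dim level of Lepr, so its fold and rank are approximate. Among the 10 largest falls were also the carboxylesterase gene Ces2b (-2.71 ± 0.28), the lysophospholipid transporter gene Mfsd2a (-2.67 ± 0.35), the oxysterol hydroxylase gene Cyp7b1 (-2.61 ± 0.48) and the protease inhibitor gene Pzp (-2.59 ± 0.41). The histone gene H3c15 fell by 3.04 ± 0.28, but histone H3 genes are nearly identical in sequence, so its probes need not measure this copy alone. Hrg, which encodes a plasma glycoprotein, fell by 2.74 ± 0.65.

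The largest rises included genes of fatty acid handling. Fabp1, which encodes a fatty acid binding protein, rose from 6.28 ± 0.44 to 8.95 ± 0.82, a 6.37-fold rise (2.67 ± 0.37, adjusted p = 0.00391), and the fatty acid hydroxylase gene Cyp4a14 rose 5.44-fold (2.44 ± 0.22, adjusted p = 0.000376); Cyp4a14 lies within 20 Mb of Lepr. The other large rises were in the glutathione transferase gene Gstp3 (2.24 ± 0.36), the cation transport gene Atp13a4 (2.21 ± 0.36, from a dim 4.37 in db/m), the complement protease gene Masp1 (2.10 ± 0.31), the epithelial stress gene Sprr1a (2.09 ± 0.50), Crybg2 (1.97 ± 0.18), the fibrinogen gene Fgg (1.95 ± 0.42), the keratin gene Krt19 (1.92 ± 0.42) and Nkain1 (1.79 ± 0.28). Sprr1a, Fgg, Krt19 and Hrg kept their call in 2, 5, 4 and 3 of the 10 fits that each left out 1 array, with adjusted p up to 0.0955, 0.0641, 0.0727 and 0.0862 without db/m 3, while the other 16 of these genes kept it in all 10 fits. Lepr itself was dim, at 4.56 ± 0.09 in db/m and 4.48 ± 0.14 in db/db, and was not past the threshold (-0.08 ± 0.08, adjusted p = 0.637). Its value does not test for the mutation.

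**Figure D2:**
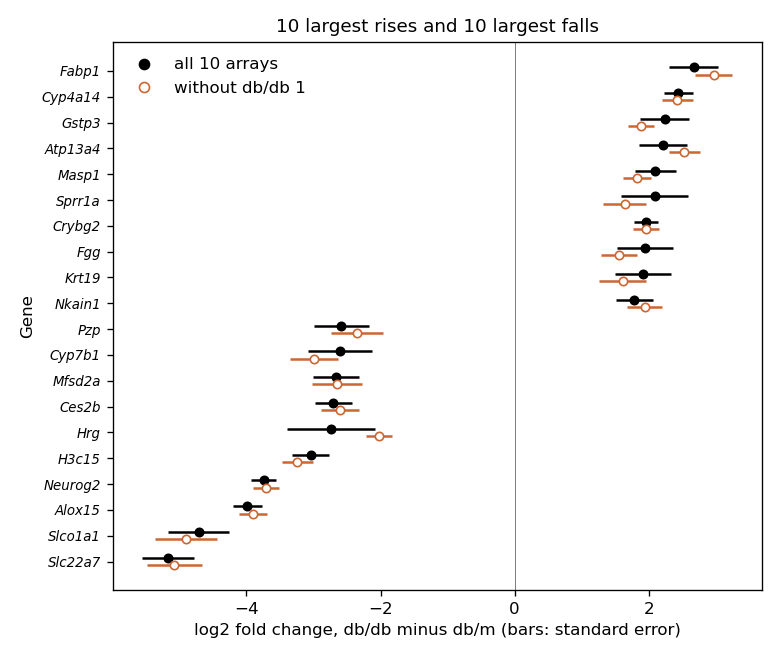
Log2 change, db/db minus db/m, of the 10 genes with the largest rise and the 10 with the largest fall, with standard errors, for all 10 arrays (filled) and without db/db 1 (open). Slc22a7 changed by -5.17 with all arrays and by -5.07 without db/db 1.

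Across all genes, limma with Benjamini-Hochberg adjustment called 1072 genes at an adjusted p under 0.05, of which 488 were higher and 584 lower in db/db. At least a 2-fold change was reached by 112 of the higher and 126 of the lower genes. For 961 of the called genes all 5 mice of one group lay on one side of the 5 of the other. Among all genes tested 1679 were separated in this way, 10.2% against 0.794% by chance. Without db/db 1 the count was 2104 (1127 higher and 977 lower), with 1069 genes called in both fits with the same sign. Leaving out db/db 1 lowered the median residual SD from 0.198 to 0.155, and without db/db 1 and db/db 2, a choice made after seeing the data, 989 genes were higher and 845 lower. The count also moved by more than 1.5 times without db/m 3 (490), db/m 4 (576), db/db 2 (644), db/db 3 (674), db/m 5 (683) and db/m 1 (684). The split between directions depended on scaling: with each array centred on its median, 363 genes were higher and 751 lower.

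In energy metabolism, 4 of 15 glycolysis genes and 2 of 12 glucose synthesis genes rose. The pyruvate kinase genes Pklr (0.80 ± 0.17, adjusted p = 0.0212) and Pkm (0.64 ± 0.13, adjusted p = 0.0168) rose, as did the aldolase gene Aldoc (0.76 ± 0.18, adjusted p = 0.0385) and the hexokinase gene Hk1 (0.63 ± 0.15, adjusted p = 0.0378). In the fit without db/db 1 these 4 genes rose by 0.68, 0.53, 0.90 and 0.58. The glucose synthesis genes that rose were Fbp2, which encodes fructose bisphosphatase (0.83 ± 0.14, adjusted p = 0.0102), and the mitochondrial carboxykinase gene Pck2 (0.58 ± 0.11, adjusted p = 0.0152). Of the 15 glycolysis genes measured 4 rose and 0 fell by limma, the same counts adjusted over the list alone, and the median change was 0.57, or 0.22 without db/db 1. Camera gave an adjusted p = 0.00392 for the list, and adjusted p = 0.244 with an estimated correlation. For the 12 glucose synthesis genes 2 rose and 0 fell, also adjusted over the list alone, with a median of 0.08 and a camera adjusted p = 0.0466, and adjusted p = 0.824 with an estimated correlation. The fit without db/db 1 had 3 rises and a median of 0.16, with camera adjusted p = 0.00191, and adjusted p = 0.353 with an estimated correlation. The camera call was kept in 4 of the 10 leave-one-out fits; it was lost without db/m 1, db/m 2 and any of db/db 2 to 5, with adjusted p up to 0.111. Pklr, Pkm, Aldoc and Hk1 kept their calls in 7, 9, 2 and 4 of those fits, with adjusted p up to 0.0633, 0.0501, 0.0965 and 0.101 without db/m 3, while Fbp2 and Pck2 kept theirs in all 10.

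The mitochondrial lists held few changed genes. Many of their members were bright, such as Atp5a1 at 13.8 ± 0.02 in db/m on a scale that ended at 14.5. Whether differences are compressed at that level was not tested. Pdk1, a kinase gene that restrains pyruvate entry into the TCA cycle, rose 2.15-fold (1.10 ± 0.15, adjusted p = 0.00363) and was the 1 called gene of 26 measured in the TCA cycle list, also adjusted over the list alone. No member of the 23 fatty acid oxidation, 44 oxidative phosphorylation and 22 branched-chain amino acid genes passed in the limma fit, with the lowest adjusted p at Eci1 (0.28 ± 0.09, adjusted p = 0.106), Cycs (-0.99 ± 0.28, adjusted p = 0.0624) and Ivd (-0.47 ± 0.13, adjusted p = 0.0632). At an unadjusted p under 0.05 these lists held 2, 2 and 3 genes. When db/db 1 was left out, Cycs, which encodes cytochrome c, and the leucine enzyme gene Ivd fell (adjusted p = 0.00334 and 0.00704). In that fit the carnitine transferase gene Cpt1b rose by 0.54 (adjusted p = 0.0111), the aminotransferase gene Bcat2 by 0.43 (adjusted p = 0.0225) and the TCA cycle list's Pdk4 by 0.65 (adjusted p = 0.0479). The list medians were -0.05, -0.02, -0.03 and -0.18 for these 4 lists in that order, or 0.02, 0.02, 0.02 and -0.02 without db/db 1, and camera adjusted p was 0.744, 0.694, 0.744 and 0.0954. For the branched-chain list camera passed without db/db 3 (adjusted p = 0.0448) and without db/db 4 (0.037). In the TCA cycle list the mean, 0.02, was opposite in sign to the median and the test, and in the fatty acid oxidation list the median was opposite in sign to the mean and the test.

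Other amino acid enzymes changed in both directions. Kynu, of tryptophan breakdown, rose by 1.91 ± 0.38 (adjusted p = 0.0172) and the ornithine aminotransferase gene Oat rose by 0.51 ± 0.11 (adjusted p = 0.0207). The aspartate oxidase gene Ddo fell by 0.80 ± 0.11 (adjusted p = 0.00409) and the cystathionine synthase gene Cbs fell by 0.64 ± 0.12 (adjusted p = 0.0149). These were the called genes among 29 measured, and 3 rose and 2 fell adjusted over the list alone; 6 rose and 4 fell without db/db 1. Camera gave an adjusted p = 0.946, and the mean was opposite in sign to the median, -0.08, and the test; without db/db 1 the median was 0.05 and the test turned upward. Without db/m 3 the adjusted p was 0.0519 for Kynu and 0.0633 for Oat, which kept its call in 7 of 10 leave-one-out fits.

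Of 25 lipid genes that PPAR-alpha controls 6 rose and 2 fell. Besides Fabp1 and Cyp4a14, the lipase inhibitor gene Angptl4 rose by 1.56 ± 0.33 (adjusted p = 0.0233), while the fatty acid uptake gene Cd36 fell 4.33-fold (-2.12 ± 0.22, adjusted p = 0.000739). In fatty acid elongation Elovl6 rose by 0.71 ± 0.12 (adjusted p = 0.00787) and Elovl7 fell by 0.40 ± 0.09 (adjusted p = 0.0302). Among peroxisomal genes the thioesterase gene Acot3 rose by 1.02 ± 0.20 (adjusted p = 0.0173) and Acot12 fell by 0.58 ± 0.15 (adjusted p = 0.0439). The ketone body enzyme gene Bdh1 fell by 1.81 ± 0.26 (adjusted p = 0.00409), and the sterol genes Cyp51 and Mvd fell by 1.73 ± 0.26 (adjusted p = 0.00534) and 0.64 ± 0.16 (adjusted p = 0.0473). Adjusted over the list alone 10 PPAR-alpha genes rose and 5 fell, with camera adjusted p = 0.00505, and adjusted p = 0.368 with an estimated correlation. Over all genes 7 rose and 3 fell without db/db 1. The called genes numbered 1 higher and 1 lower of 20 peroxisomal genes, 1 lower of 6 ketone genes, 1 higher and 1 lower of 19 fatty acid synthesis genes and 2 lower of 17 cholesterol genes. Adjusted over the list alone these were 2 and 2, 1 and 3, 1 and 3, and 0 and 2, and without db/db 1 they were 3 and 2, 0 and 2, 1 and 3, and 0 and 3. Camera called none of the 4 lists (adjusted p = 0.958, 0.402, 0.402 and 0.0514), and in the peroxisomal list the mean was opposite in sign to the median and the test. The cholesterol list passed without db/m 3 (0.0329), db/db 2 (0.019), db/db 3 (0.0471) and db/db 4 (0.0281). Angptl4, Acot3, Acot12, Elovl7 and Mvd kept their calls in 7, 9, 2, 2 and 2 of the leave-one-out fits, with adjusted p up to 0.0626 without db/m 4, 0.0531 and 0.11 without db/m 3, 0.075 without db/db 2 and 0.112 without db/m 3.

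Of 8 genes typical of the last segment of the proximal tubule, S3, 4 fell. Besides Slc22a7, Slco1a1 and Cyp7b1, the acyl-CoA synthetase gene Acsm3 fell by 1.55 ± 0.13 (adjusted p = 0.000338). The cystine and aspartate transporter gene Slc7a13 was not past the threshold with all arrays (-1.72 ± 0.48, adjusted p = 0.0624) and was past it without db/db 1 (-1.21, adjusted p = 0.00195). The glucose transporter gene Slc5a1 (0.43 ± 0.15, adjusted p = 0.123), Slc22a13 (-0.61 ± 0.32, adjusted p = 0.297) and the water channel gene Aqp1 (-0.04 ± 0.07, adjusted p = 0.814) did not pass. Adjusted over the list alone 5 fell and 1 rose, and 5 fell without db/db 1, with a median of -1.64, or -1.35 without db/db 1. Camera gave an adjusted p = 0.000146 in the lower direction, and adjusted p = 0.244 with an estimated correlation. The list was below the db/m mean in 5 of 5 db/db mice, from -1.03 to -1.66, and at -1.56 in db/db 1.

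Of 9 podocyte genes 5 rose, although the tissue had been depleted of glomeruli. The cell cycle inhibitor gene Cdkn1c rose by 0.80 ± 0.19 (adjusted p = 0.0357), the intermediate filament gene Nes by 0.71 ± 0.11 (adjusted p = 0.0056), the receptor phosphatase gene Ptpro by 0.58 ± 0.10 (adjusted p = 0.01) and the actin-binding gene Synpo by 0.46 ± 0.08 (adjusted p = 0.0107). Adjusted over the list alone 6 rose, and 7 rose without db/db 1. The median was 0.46, with camera adjusted p = 6.67e-05, and adjusted p = 0.244 with an estimated correlation. Cdkn1c kept its call in 2 of 10 leave-one-out fits, with adjusted p up to 0.0861 without db/m 4. The other glomerular lists did not pass: in the endothelial list Pecam1 was nearest the threshold (0.29 ± 0.08, adjusted p = 0.0546, or 0.0469 without db/db 1; 1 of 13 genes rose adjusted over the list alone, camera adjusted p = 0.322), and in the mesangial and smooth muscle list Rgs5 rose by 0.88 ± 0.18 (adjusted p = 0.018; 2 of 10 genes rose adjusted over the list alone, camera adjusted p = 0.317). Rgs5 reached an adjusted p of 0.0525 without db/m 3.

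Markers of the other tubule segments changed little with all 10 arrays. For S1 and S2 the gene nearest the threshold among 12 was Acsm2 (-0.16 ± 0.07, adjusted p = 0.194), and the glucose transporter gene Slc5a2 was at -0.05 ± 0.20 (adjusted p = 0.92). In the thick ascending limb the claudin gene Cldn10 fell by 0.23 ± 0.06 (adjusted p = 0.0433), and in the distal convoluted and connecting tubule the magnesium channel gene Trpm6 rose by 0.60 ± 0.14 (adjusted p = 0.0356); they kept the call in 1 and 3 of 10 leave-one-out fits, with adjusted p up to 0.125 and 0.0965 without db/m 3. The sodium channel gene Scnn1b, in the principal cell list, had a change of 0.57 ± 0.20 (adjusted p = 0.135) and was past the threshold without db/db 1 (0.77, adjusted p = 0.00156). The proton pump gene Atp6v0d2, an intercalated cell marker, was at 0.24 ± 0.21 (adjusted p = 0.558). Camera adjusted p was 0.922 for S1 and S2, 0.328 for the thick ascending limb, 0.202 for the distal tubule, 0.328 for principal cells and 0.862 for intercalated cells, with the mean opposite in sign to the median and the test in the S1 and S2 and the intercalated lists. Cldn10 and Trpm6 were the called genes of these lists, also adjusted over the list alone. After db/db 1 was left out, camera called the distal list (adjusted p = 0.00035), principal cells (0.0073) and intercalated cells (0.0434), all higher in db/db, and with an estimated correlation adjusted p = 0.353, 0.393 and 0.629. In that fit 5 distal, 4 principal cell and 1 intercalated gene rose. In db/db 1 the distal list stood at -0.767 and the intercalated list at -1.35.

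Transport genes of the proximal tubule rose in part. The urate transporter gene Slc2a9 rose by 0.86 ± 0.17 (adjusted p = 0.0168) and the sugar transporter gene Slc5a10 by 0.47 ± 0.08 (adjusted p = 0.00916). Of the 27 genes 2 rose and 0 fell, or 2 and 1 adjusted over the list alone, with a camera adjusted p = 0.15. Without db/db 1, in which the list stood at -0.293, 6 rose and 2 fell and camera gave an adjusted p = 0.00051, and adjusted p = 0.353 with an estimated correlation.

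Tubular injury and repair genes rose in part. Besides Fgg and Krt19, the cell cycle inhibitor gene Cdkn1a rose by 1.77 ± 0.34 (adjusted p = 0.0154) and the keratin gene Krt18 by 1.17 ± 0.22 (adjusted p = 0.0131), both called in all 10 leave-one-out fits. Fgg and Krt19 kept the call in 5 and 4 of those fits, with adjusted p up to 0.0641 and 0.0727 without db/m 3. The injury genes Lcn2 (3.20 ± 1.37, adjusted p = 0.211) and Havcr1 (1.17 ± 1.30, adjusted p = 0.652) did not pass. Without db/db 1 their changes were 2.28 and -0.21, so that of Havcr1 turned. Of the 18 genes 5 rose and 0 fell, the same adjusted over the list alone, and 7 rose without db/db 1. The median was 1.17, or 0.46 without db/db 1, with camera adjusted p = 1.63e-07, and adjusted p = 0.824 with an estimated correlation. By mouse the list stood at 3.13 in db/db 1, at 1.01 in db/db 2 and between 0.29 and 0.40 in the other db/db mice. In db/db 1 and 2 neutrophil markers stood at 5.31 and 2.27 and macrophage markers at 2.80 and 0.96.

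Inflammation, complement, interferon and matrix genes were high in db/db 1, and few passed as a group difference. Sele, an endothelial adhesion gene, rose by 0.38 ± 0.10 (adjusted p = 0.0485) from a dim 4.70 in db/m. It was the 1 called gene of 24 in the inflammation list, with 0 adjusted over the list alone. Sele kept the call in 2 of 10 leave-one-out fits, with adjusted p up to 0.123 without db/m 3. The antigen presentation gene H2-Ab1 (0.94 ± 0.35, adjusted p = 0.146, or 0.0241 without db/db 5) and the RNA sensor gene Ifih1 (0.50 ± 0.25, adjusted p = 0.274) were nearest the threshold in the complement and interferon lists. In the matrix list Thbs1, which encodes thrombospondin, rose by 0.66 ± 0.12 (adjusted p = 0.0134), the 1 called gene of 29, also adjusted over the list alone. Camera called the inflammation list (median 1.02, adjusted p = 0.000407), the complement list (0.47, adjusted p = 0.000723), the interferon list (0.58, adjusted p = 0.00959) and the matrix list (0.30, adjusted p = 0.00551), and for each of them adjusted p = 0.824 with an estimated correlation. When db/db 1 was left out none of the 4 passed (adjusted p = 0.108, 0.205, 0.534 and 0.534), the medians were 0.29, 0.27, 0.10 and 0.07, 3 inflammation and 2 matrix genes rose, and 1 inflammation, 1 interferon and 1 matrix gene fell. The inflammation list stood at 4.55 in db/db 1 and 0.93 in db/db 2, and between -0.11 and 0.30 in db/db 3 to 5.

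Leukocyte markers differed widely among the db/db mice. The neutrophil genes, such as Ltf (1.96 ± 0.95, adjusted p = 0.268, or 1.04 without db/db 1), stood at 5.31 in db/db 1, 2.27 in db/db 2 and between -0.11 and 0.50 in the others. Macrophage and dendritic cell genes, such as Itgam (0.59 ± 0.47, adjusted p = 0.518, or 0.07 without db/db 1), stood at 2.80 in db/db 1 and 0.96 in db/db 2, and between -1.02 and -0.62 in the others. For T and NK cells the gene nearest the threshold was Ccl5 (1.05 ± 0.93, adjusted p = 0.562, with a change of 0.06 without db/db 1). For B and plasma cells it was the immunoglobulin chain gene Jchain (-1.08 ± 0.34, adjusted p = 0.0939, or adjusted p = 0.0247 without db/db 1). Camera called the neutrophil list (median 1.46, adjusted p = 0.00946; adjusted p = 0.824 with an estimated correlation) and not the macrophage, T cell and B cell lists (adjusted p = 0.322, 0.413 and 0.799). Leaving out db/db 1 turned the macrophage and T cell medians from 0.27 and 0.19 to -0.285 and -0.203. Limma called 0 genes in these 4 lists, and Jchain alone had an unadjusted p under 0.05. The neutrophil list without db/db 1 had a median of 0.69 and a camera adjusted p = 0.0385, and adjusted p = 0.629 with an estimated correlation.

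**Figure D3:**
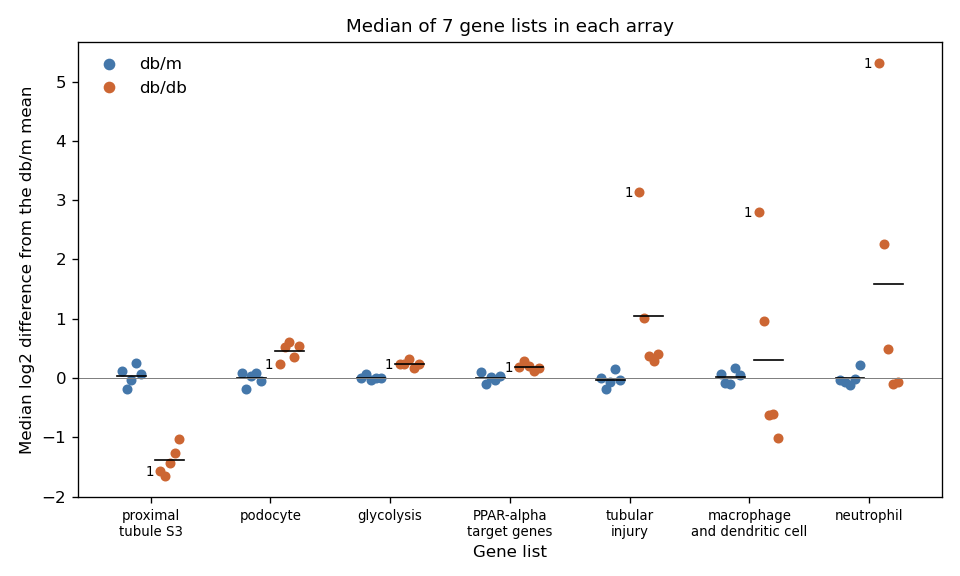
Median log2 difference from the db/m mean over the genes of 7 lists in each of the 10 arrays, with 1 point per mouse, db/db 1 marked 1 and black bars for group means. The S3 list lies at -1.03 or lower in all 5 db/db mice, whereas the neutrophil list ranges from -0.11 to 5.31 among them.

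Stress responses changed in several directions. The epoxide hydrolase gene Ephx1 rose by 1.23 ± 0.12 (adjusted p = 0.000495) and the metallothionein genes Mt1 and Mt2 rose by 0.85 ± 0.07 (adjusted p = 0.000283) and 0.81 ± 0.10 (adjusted p = 0.00212), while Gclc, of glutathione synthesis, fell by 0.63 ± 0.16 (adjusted p = 0.0439). The genes that fell in the early response list were 3 heat shock genes: Hspa1a by 2.40 ± 0.41 (adjusted p = 0.00914), Hspa1b, which is nearly identical to it in sequence, by 1.88 ± 0.37 (adjusted p = 0.0173) and Hsph1 by 1.06 ± 0.12 (adjusted p = 0.00123). In the same early response list Ier3 rose by 0.89 ± 0.15 (adjusted p = 0.00914). The endoplasmic reticulum chaperone genes Dnajb11 and Dnajc3 fell by 0.52 ± 0.12 (adjusted p = 0.0352) and 0.26 ± 0.07 (adjusted p = 0.0441). The unfolded protein response list had 0 genes higher and 2 lower of 24, or 0 and 6 adjusted over the list alone, with camera adjusted p = 0.0439 in the lower direction, and adjusted p = 0.824 with an estimated correlation. In db/db 1 this list stood at 0.0323, and without that mouse 1 gene rose and 10 fell. The camera call was lost without db/m 4, db/m 5 and any of db/db 2 to 5, with adjusted p up to 0.147. In the NRF2 list 3 of 24 genes rose and 2 fell, or 4 and 2 adjusted over the list alone, with a camera adjusted p = 0.0836, or 0.0443 without db/db 1, where 5 rose and 2 fell, and there adjusted p = 0.353 with an estimated correlation. In the early response list 1 of 17 genes rose and 3 fell, or 2 and 4 adjusted over the list alone, with a camera adjusted p = 0.832 and the mean opposite in sign to the median and the test. Gclc, Dnajb11 and Dnajc3 kept their calls in 2, 4 and 1 of 10 leave-one-out fits, with adjusted p up to 0.101 without db/m 1, and 0.0838 and 0.103 without db/m 4.

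Genes of the hypoxia response, the clock, blood pressure control and drug metabolism also changed. The collagen prolyl hydroxylase gene P4ha1 fell by 0.97 ± 0.14 (adjusted p = 0.00422). Egln3, a prolyl hydroxylase gene of oxygen sensing, rose by 0.82 ± 0.13 (adjusted p = 0.00787), and the vasodilator peptide gene Adm rose by 0.82 ± 0.18 (adjusted p = 0.0255). The clock genes Per1 and Cry1 rose by 1.35 ± 0.21 (adjusted p = 0.00658) and 0.77 ± 0.19 (adjusted p = 0.0401). Ace, the angiotensin-converting enzyme gene, fell 3.3-fold (-1.72 ± 0.23, adjusted p = 0.00364), and the sodium-retaining kinase gene Sgk1 rose by 0.41 ± 0.08 (adjusted p = 0.0201). The monooxygenase gene Fmo5 fell by 2.32 ± 0.27 (adjusted p = 0.00155), and Cyp24a1, which degrades vitamin D, rose by 1.48 ± 0.26 (adjusted p = 0.0101). Of 16 hypoxia genes 3 rose and 1 fell, of 18 clock genes 2 rose, of 15 renin-angiotensin and sodium genes 1 rose and 1 fell, and of 22 xenobiotic genes 5 rose and 6 fell. Adjusted over the list alone these counts were 6 and 3, 2 and 0, 3 and 1, and 6 and 10, and without db/db 1 they were 5 and 2, 5 and 0, 7 and 1, and 6 and 6. Camera adjusted p was 0.322, 0.317, 0.159 and 0.471 in that order, and without db/db 1 the clock (0.0434) and renin-angiotensin (0.0043) lists passed, with adjusted p = 0.486 and 0.444 with an estimated correlation. Adm, Cry1 and Sgk1 kept their calls in 4, 2 and 9 of 10 leave-one-out fits, with adjusted p up to 0.0656 without db/m 4, 0.0826 without db/m 2 and 0.063 without db/m 3.

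Cell division genes rose in part. The replication helicase gene Mcm5 rose by 1.07 ± 0.26 (adjusted p = 0.0367) and the nucleotide synthesis gene Rrm2 by 1.02 ± 0.22 (adjusted p = 0.0226), keeping the call in 3 and 6 of 10 leave-one-out fits, with adjusted p up to 0.088 without db/m 4 and 0.0673 without db/m 3. Of the 19 genes 2 rose and 0 fell, or 3 and 0 adjusted over the list alone, and 4 rose without db/db 1. The median was 0.86, or 0.56 without db/db 1, with camera adjusted p = 6.19e-05, and adjusted p = 0.824 with an estimated correlation. The list stood at 1.67 in db/db 1, at 1.56 in db/db 2 and between 0.16 and 0.36 in the others. The neutrophil (5.31 and 2.27) and macrophage (2.80 and 0.96) lists were raised in the same pair of mice.

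The remaining lists showed little change with all 10 arrays. The fibroblast list differed among the db/db mice, at 1.32 in db/db 1, 0.31 in db/db 2 and between -0.69 and -0.34 in the others. The lipase gene Lpl, in the adipocyte list, fell by 1.02 ± 0.23 (adjusted p = 0.03), with the call kept in 4 of 10 leave-one-out fits and an adjusted p up to 0.0749 without db/m 4. The growth factor binding gene Igfbp3 (-0.62 ± 0.18, adjusted p = 0.0756), the pentose pathway gene Tkt (0.30 ± 0.08, adjusted p = 0.0587, or 0.0121 without db/db 1), the collagen gene Col1a2 (0.74 ± 0.57, adjusted p = 0.503, with a change of 0.16 without db/db 1), the heme synthesis gene Alas2 (0.20 ± 0.36, adjusted p = 0.792) and the myosin gene Myh4 (0.11 ± 0.12, adjusted p = 0.623) did not pass. The Y-linked gene Uty was at 7.62 in db/m and 7.24 in db/db (-0.38 ± 0.12, adjusted p = 0.095, or 0.0394 without db/db 4). The genes past the threshold adjusted over the list alone were Tkt, Lpl and Uty. Camera adjusted p was 0.328 for insulin and leptin signalling, 0.223 for the polyol and pentose pathways, 0.63 for fibroblasts, 0.744 for erythroid cells (2 genes measured), 0.451 for adipocytes, 0.744 for skeletal muscle, where the median was opposite in sign to the mean and the test, and 0.317 for the sex-linked genes.

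Over the 46 lists, camera called 13 with all 10 arrays, 11 of them higher and 2 lower in db/db, and fry, which tests each list by itself, called 5. By fry with all arrays the called lists were S3 (adjusted p = 0.000444), NRF2 (0.00287), glycolysis (0.00489), podocyte (0.00489) and PPAR-alpha (0.0139). With an estimated correlation camera called 0 lists, both with all arrays and without db/db 1 (5 and 5 lists at an unadjusted p under 0.05). With the preset correlation and without db/db 1 it called 16 lists, 9 of them also called with all arrays in the same direction. Since 74 of 100 sampled splits of the same arrays gave at least 13 called lists (highest 28), the number of list calls did not stand out from other groupings; without db/db 1, 8 of 100 splits gave at least 16 (highest 19).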

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

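The tests of RNA degradation, hybridisation, leukocytes, a larger form of the others' change, a wrong label, S3 cell number and residual glomeruli were chosen after the result was seen; the lists of male-biased, female-biased and second podocyte genes were chosen after the main result but before their own values were seen.

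A search covered 298 sets of 5 values, each 1 measure in 1 group of mice. It looked for a mouse lying far from the other 4, with a gap over 0.71 of the range. This picked out 38, against 14.9 by chance at about 1 in 20 groups, and 33 of them were in db/db 1. That mouse stood at 108 on the first principal component and 8.71 on the second. Its medians against the db/m mean were lower than in the other db/db mice for the TCA cycle (-0.323), fatty acid oxidation (-0.256), oxidative phosphorylation (-0.228), branched-chain (-0.664) and other amino acid catabolism (-0.556), peroxisomal oxidation (-0.2), ketone (-0.506) and cholesterol (-0.694) genes. They were also lower for proximal transport (-0.293), S1 and S2 (-0.544), distal tubule (-0.767), intercalated cell (-1.35) and erythroid (-1.54) genes. The erythroid list had 2 genes measured, Alas2 and Slc4a1, and Slc4a1 is also in the intercalated list. In db/db 1 Slc4a1 was at -3.03 from the db/m mean, while Alas2 was at 4.92 against a db/m mean of 4.96. The erythroid value is thus not a separate red cell signal. The medians of db/db 1 were higher for the unfolded protein response (0.0323), tubular injury (3.13), inflammation (4.55) and T and NK cells (2.64). By gene, db/db 1 was high for Gstp3 (10.6), Pkm (13.2), Angptl4 (13.1), Krt18 (13), P4ha1 (9.86) and Itgam (7.49). It was low for Hrg (4.05), Cycs (7.06), Ivd (12.3), Kynu (9.91), Cbs (11.8), Acot3 (10.8), Elovl6 (9.82) and Scnn1b (9.58). Outside that mouse, the erythroid list was high in db/m 4 (0.858), Nkain1 in db/m 5 (7.28), Hrg in db/m 5 (10), Slc5a10 in db/db 2 (13.7) and Mt1 in db/m 2 (12.5).

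Mouse db/db 1 carried a neutrophil, acute-phase and injury profile. The tables argue against degraded RNA, since its actin control difference between the 3' and 5' ends, 0.716, was below the other arrays (0.991 to 1.89). They argue against failed hybridisation, since its controls lay 0.031 log2 units from the others' range. Of the genes called without db/db 1, 76.1% deviated the same way in it. Both sides of that share use the same db/m arrays, which raises it, so it argues against a wrong group label only in part. The genes over 4-fold higher in db/db 1 had a median change of 0.145 in db/db 2 to 5, and -0.0136 in db/db 3 to 5. A larger form of the change in db/db 3 to 5 is thus argued against for those genes. These medians do not test db/db 2 by itself, in which Lcn2 and Cxcl2 were also raised, by 4.87 and 4.83, while Orm2 was at 0.13. For db/db 1 as a whole, r across genes, which are not independent, was 0.333, and the shared diabetic state cannot be told apart. This r lay between the bounds set. It was 0.27 to 0.337 (median 0.294) with separate db/m mice on each side, 0.188 against db/db 3 to 5 and 0.593 against db/db 2. Leukocytes in the tissue may account for part of the profile of db/db 1, with the 8 neutrophil markers at 5.31, S100a8 at 13.5 and S100a9 at 14.0 against 7.31 and 8.996 in db/m. The db/m means of the 8 markers were 4.01 to 8.996, the lowest near background, and no other biological explanation was tested.

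The falls of S3 markers in db/db were present in 5 of 5 mice, with a mean of -1.998 ± 0.184 over the 8 genes. Fewer S3 cells as the whole cause would lower all 8 markers alike. The falls were unequal, with Slc22a7 at -5.17 ± 0.39 and Slco1a1 at -4.71 ± 0.46. Slc7a13 was at -1.72 ± 0.48, Acsm3 at -1.55 ± 0.13 and Slc22a13 at -0.61 ± 0.32. For these markers the values argue against that cause, as far as each marker is made in S3 alone. The 2 markers Slc5a1 and Aqp1 lay more than 2 standard errors above -0.818, but this bound was set after their values were seen. Aqp1 is also made in other segments, so the test with this bound rests mainly on Slc5a1. A partial loss of S3 cells stays open. Lower male-biased expression may contribute, as Slco1a1 and Cyp7b1 are known to be male-biased in mouse kidney: 6 further male-biased genes were lower by 0.538 (mean -0.538 ± 0.0712, exact permutation p = 0.00794, the smallest possible, adjusted p = 0.0198 over the 5 added lists), with Hsd11b1, Odc1, Kap and Nudt19 past the limma threshold. The 3 female-biased genes had a mean of 0.634 ± 0.263 (exact permutation p = 0.0476, adjusted p = 0.0794), carried by Abcc3, so a shift towards female-biased expression cannot be told apart from a change of that gene. Mice of different sex are argued against as the source. The sex-linked list, with 3 genes measured, stood between -0.305 and 0.0494 in all 10 arrays, and its Y-linked gene Uty between 6.86 and 7.68. Several male-biased genes are proximal tubule genes themselves, no hormone was measured, and the diabetic state of the group stays open as an untested explanation.

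The rise of podocyte markers had a mean of 0.416 ± 0.0756 over 9 genes. More residual glomeruli cannot be told apart from other causes, since 4 other glomerular markers had a mean of 0.147 ± 0.132 (exact permutation p = 0.286), a spread that holds both no change and the size needed, and without db/db 1 a mean of 0.270 ± 0.0587 (exact permutation p = 0.00794, the smallest possible), with Plat past the limma threshold in both fits. A second list of 3 podocyte genes had a mean of -0.0283 ± 0.113 (exact permutation p = 0.881), or 0.0728 ± 0.0524 without db/db 1 (exact permutation p = 0.238). Its genes went both ways, with Thsd7a at 0.28, Tdrd5 at -0.07 and Rhpn1 at -0.30. The change may be limited to the markers listed first, but these 3 genes cannot decide it. A difference in how far glomeruli were removed and a change in the podocytes themselves both stay open.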

How the results depend on the processing

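The fits without both db/db 1 and db/db 2, with both the replicate block and db/db 1 left out, and of calls near Lepr without db/db 1, were chosen after seeing the data. Called genes numbered 488 higher and 584 lower. With the mouse number as a replicate block they were 180 and 213; the numbers do not pair the mice, since the deviations of same-numbered mice from their group means correlated across genes at -0.0948 to 0.00599. With array weights, which gave db/db 1 a weight of 0.102, they were 1346 and 1295, with at least a 1.5-fold change 311 and 264, at an adjusted p under 0.01 132 and 147, and without db/db 1 and 2 989 higher. Leaving out 1 array gave 234 to 1127 higher and 256 to 977 lower; leaving out any array other than db/db 1 lowered the total, and the highest values came without db/db 1. The glycolysis median of 0.571 was no longer past the threshold with an estimated correlation (adjusted p = 0.244). The glucose synthesis median was past it with all arrays and not with dim genes left out (0.0839, adjusted p = 0.0835), with centred arrays (0.0161, 0.0815), with an estimated correlation (0.0839, 0.824) or by fry (0.0839, 0.34), and ranged from 0.0515 to 0.176 with arrays left out. The branched-chain median ranged from -0.223 to 0.0213, the latter without db/db 1 and 2, and passed without db/db 3 or 4. The odds ratio near Lepr was 1.31 for 10 Mb and 1.22 without db/db 1. The direction of the list test reversed as follows, by median change. With db/db 1 alone left out, the TCA cycle (0.0218), oxidative phosphorylation (0.02), other amino acid (0.0525), peroxisomal (0.0152), early response (-0.0357), fibroblast (-0.133), S1 and S2 (0.131), macrophage (-0.285) and T and NK (-0.203) lists reversed. Over all fits that left out arrays, including the one without db/db 1 and 2, the TCA cycle ranged from -0.0744 to 0.0262, oxidative phosphorylation from -0.0446 to 0.0208, other amino acids from -0.129 to 0.0614, peroxisomal genes from -0.0481 to 0.0152 and early response genes from -0.0842 to 0.307. Intercalated cells ranged from -0.141 to 0.336, B and plasma cells from -0.445 to 0.119, Col1a2 from -0.171 to 1.05 and Ccl5 from -0.355 to 1.47. Without db/db 1 and 2 the matrix list, called higher with all arrays, was called lower at -0.128 (adjusted p = 0.0431; up to 0.526 with other arrays left out). In the same fit inflammation stood at 0.00409 (up to 1.33), complement at 0.0502 (up to 0.645), interferon at -0.154 (up to 0.905). Past the threshold there, and in the opposite direction, were fibroblast at -0.538 (adjusted p = 0.0108; up to 0.149), S1 and S2 at 0.133 (0.0431; down to -0.0665), macrophage at -0.651 (2.41e-08; up to 0.705) and T and NK cell at -0.407 (0.00017; up to 0.416). With array weights the TCA cycle (0.0166), oxidative phosphorylation (0.0195), other amino acid (0.0348), peroxisomal (-0.0124), early response (0.0313), fibroblast (-0.168), S1 and S2 (0.112), macrophage (-0.31) and T and NK (-0.217) lists reversed. With both the replicate block and db/db 1 left out, the same lists stood at 0.00865, 0.0152, 0.0717, 0.0219, -0.138, -0.128, 0.123, -0.283 and -0.233 (adjusted p = 0.0388 for this last, T and NK), and Ccl5 at -0.0253. Quantile normalisation reversed oxidative phosphorylation (-0.0088), other amino acid (-0.087), peroxisomal (-0.0166) and S1 and S2 (-0.0239) lists, centring reversed other amino acids (-0.151), and fry gave the opposite direction for early response (0.0887) and intercalated (0.0246) genes. The cause was not tested beyond these fits. Of the alternatives for the lists and counts that answer a comparison, 130 kept direction and side of the threshold, or stayed within 1.5 times the count, 24 counts moved, 13 lost the threshold, 2 gained it and 16 reversed; of those for other lists and named genes, 2213 did, 279 lost the threshold, 56 gained it and 49 reversed. The mean of several values per gene was not run, since each gene had 1 value. Dim genes such as Lepr lie near background, where arrays compress differences.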

Other observations

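The test of added chaperone genes was chosen after the heat shock falls were seen but before its own values were; the rule that a Lepr result must also hold without db/db 1, the calls without that mouse, and the split count of lists without it, were chosen after seeing the data. The genes named in the next paragraph were also chosen after their values were seen.

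Cyp27b1, which activates vitamin D, rose by 0.90 ± 0.17 (adjusted p = 0.0159), alongside the degrading enzyme gene Cyp24a1. The genes of the epithelial sodium channel, Scnn1a, Scnn1b and Scnn1g, did not pass with all 10 arrays (0.44, 0.57 and 0.68, with adjusted p = 0.351, 0.135 and 0.22) and rose without db/db 1 (0.70, 0.77 and 1.01, with adjusted p = 0.00357, 0.00156 and 0.000245). The macrophage list had 9 of 15 genes lower by limma without db/db 1 and 2.

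For the number of called genes chance was unlikely but not excluded, since splits that mix the groups also hold the group difference in their spread. The real grouping gave 1072, and of 100 sampled splits of the 126 possible 1 gave as many, the real one, with 2 in the highest other. Without db/db 1 the real grouping gave 2104, and 1 of 100 splits gave as many, with 111 in the highest other. Chance cannot be excluded for the number of called lists, 13, since 74 of 100 splits gave as many, with 28 in the highest other. Nor can it be excluded without db/db 1, where the real grouping called 16 lists and 8 of 100 splits gave as many, with 19 in the highest other. With an estimated correlation camera called 0 lists, against 5 at an unadjusted p under 0.05, so the preset correlation also bears on these counts.

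Falls of the heat shock genes Hspa1a, Hspa1b and Hsph1 may belong to a lower expression of chaperone genes as a group, as a hypothesis. A second list of 8 chaperone genes had a mean of -0.524 ± 0.0731, lower in 5 of 5 db/db mice than in any db/m mouse (exact permutation p = 0.00794, adjusted p = 0.0198 over the 5 added lists), and -0.532 without db/db 1. Hspa4l fell by 0.79 ± 0.09 (adjusted p = 0.00115), Stip1 by 0.62 ± 0.09 (adjusted p = 0.00402), Chordc1 by 0.93 ± 0.16, Dnaja1 by 0.50 ± 0.09 and Fkbp4 by 0.52 ± 0.13, while Hspa8 (-0.11 ± 0.07, adjusted p = 0.348), Hspe1 (-0.25 ± 0.11, adjusted p = 0.208) and Bag3 (-0.46 ± 0.25, adjusted p = 0.33) did not pass. Heat shock genes respond to handling of tissue, and whether the groups were handled alike was not tested.

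An inherited chromosome segment around the Lepr mutation could differ between the groups and change nearby genes. By the gene order of the RefSeq table for the mouse GRCm38 assembly, within 20 Mb of Lepr 24 of 238 genes were called, against 1003 of 15514 elsewhere, an odds ratio of 1.62 (95% interval 1.01 to 2.49, Fisher's exact p = 0.033). Without db/db 1 it was 1.22 (Fisher's exact p = 0.281), at 10 Mb 1.31 (Fisher's exact p = 0.409) and at 40 Mb 1.39 (Fisher's exact p = 0.0425). The first value met the condition written before the data were seen, but it did not hold without db/db 1, so a linked segment cannot be told apart from chance. The called genes Cyp4a14, Cyp4a10, Cyp4b1 and Cyp4a12a lie in this window, so their changes are open to the same explanation; genes in 1 segment are not independent.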
